A study of Mus musculus with 26 samples.

How the data were processed

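Gene expression was measured by RNA sequencing in 26 libraries from the aortae of C57BL6/J mice wounded by mechanical pressure. Per the labels' protocols, the endothelial fraction was collected by pushing a guanidine lysis buffer through the vessel lumen (here called the flush), the tissue fraction was the homogenized vessel left after the flush, and libraries were made with a NuGEN Ovation kit for very small amounts of RNA. The labels put the libraries in 4 groups. The injured 48 h group held flushes of the wounded abdominal aorta of 9 mice, and the uninjured 48 h group held flushes of the thoracic aorta of the same 9 mice. The injured 3 h group held abdominal flushes of 5 other mice, and the tissue 48 h group held the flushed abdominal aorta of 3 of the 48 h mice. Each replicate of a group was a separate mouse, and the labels divided the mice into 3 experimental batches. The headers of the deposited tables write a time of 0 h for the columns of the 3 h group, whereas the sample labels give 3 h, and the labels were followed.

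The authors' deposited table of raw counts gave whole-number read counts for 21119 gene symbols, of which 2407 were at 0 in every library and 23 carried a spreadsheet date in place of a symbol. HISAT2 2.0.3, HTSeq, DESeq2 1.14.1 and the mouse build GRCm38 are named per the submitters' processing notes, without the role of each. The gene annotation, the read filters and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart from those of the gene named. Counts of genes with near-identical copies, such as the beta globins Hbb-bs and Hbb-bt, the class I genes H2-D1 and H2-K1, and the olfactory and vomeronasal receptor families, are uncertain for the same reason. A second deposited table held a signal that the authors made by dividing the counts of each library by 1 size factor. The ratio was constant in each library for 100% of the genes compared, within a relative tolerance of 1e-06, and the size factors ran from 0.356 to 2.9. A table of regularized log values was not used. The authors' deposited tables of comparisons gave a log2 fold change and a Benjamini-Hochberg adjusted p-value per gene for 6 pairs of groups, and were used only for counts of genes under an adjusted p of 0.05.

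Totals ran from 1755773 to 5294304 counts in the uninjured flushes, 2657169 to 4346847 in the injured 3 h flushes, 3904901 to 11982411 in the injured 48 h flushes and 13853003 to 15560008 in the tissue libraries. No molecular identifiers are described, so reads of amplified copies are not independent molecules, and the counting intervals and floors given here cover counting error only. Against a group at 0, a fold is given as a lower bound from a floor of 3 counts over the whole group. Where a group held 1 to 3 counts, the ratio of the summed counts per total is given with its exact 95% counting interval. Within a group, correlations of log2 CPM between libraries ran from 0.77 to 0.952 (uninjured), 0.877 to 0.936 (injured 3 h), 0.79 to 0.971 (injured 48 h) and 0.988 to 0.99 (tissue). No 2 libraries of a group held identical values, and the smallest chi-square per degree of freedom between any pair was 7.21, so every library was counted as 1 sample.

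All tests used the counts as deposited. Each comparison was tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, TMM scaling, a filter on low counts by group that left 13884 genes, all 26 libraries in 1 fit, no covariate), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A gene is called higher or lower where it passed that threshold, and standard errors of log2 fold changes were taken from the quasi-likelihood F statistic. CPM values are scaled by TMM, and log2 CPM uses a prior count of 2. Gene lists and cell type markers were fixed before the data were examined, as were the main test, most of the other ways of running it and the rule for naming genes. Of 40 lists, 37 with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over 148 tests in the 4 main comparisons. The test was repeated with a correlation estimated from the data, and with fry, which asks whether a list's own genes moved, on balance, one way. The marker score of a cell type is the mean log2 CPM of its tested markers. Scores and library properties were compared with exact two-sided permutation tests, 72 in the family, adjusted by Benjamini-Hochberg. These tests regrouped the libraries freely, without the pairing by mouse, and no paired version was run.

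The text names genes by a fixed rule. In each of the 4 main comparisons it takes the 6 largest rises and 6 largest falls past the threshold among genes with a settled symbol, at least 5 CPM in the higher group and at least 80% of that group's libraries above the mean of the other. It adds up to 4 members with the smallest p from each list described, and 17 genes followed throughout. Some genes that the rule took are not reported here. Positions come from an annotation of GRCm38 and were found for 220 of the 223 genes that the rule took.

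Each edgeR comparison was first run on simulated counts with the real library sizes and a mean level per gene pooled over all 26 libraries. In them 100 genes were changed 2-fold and 100 were changed 4-fold. The changed genes were drawn from those above a minimum pooled level, so the recovered shares do not cover genes of low counts. For injured against uninjured 48 h flush, over 13153 simulated genes, edgeR recovered 54% of the 2-fold and 82% of the 4-fold changes, and 2.86% of its calls were false. For injured 48 h flush against tissue, over 13135 genes, the same shares were 47%, 84% and 6.43%.

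The uninjured and injured 48 h flushes, and the 3 tissue libraries, come from the same mice, so the mouse pairs them. Deviations from the group means of the 2 flushes of a mouse correlated between -0.127 and 0.207, and those of flush and tissue between 0.014 and 0.134. The library of the same mouse was the closest in only 1 of these 12 cases, so expression alone does not show the pairing, which rests on the labels. A fit with the mouse as a block was therefore run as well. The other choices tried were size factors from DESeq2 1.42.0, no filter and a stricter filter on low counts, the DESeq2 Wald test, voom with sample quality weights, a fit of only the 2 groups compared, batch as a covariate, each batch alone or left out, each injured 3 h or tissue replicate left out, list tests with an estimated correlation, with fry and without shared markers, marker scores on the raw totals, and an overlap limited to 2-fold changes. Added later were equal depth, deeper uninjured libraries only, injured 48 h replicate E2A left out, and a limit of 20 CPM. The injured abdominal and uninjured thoracic flushes differ in segment as well as injury. Only the comparison of the 2 times and that of flush with tissue lie within the abdominal aorta.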

Results

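The aortic endothelium is a single cell layer that closes a wound from the cells around it. The libraries followed this repair by comparing lumen flushes of the wounded abdominal aorta, taken 3 h and 48 h after injury, with flushes of the unwounded thoracic aorta and with the abdominal vessel wall left after the flush. The flush was rich in endothelial transcripts. The endothelial marker score was 7.77 ± 0.243 (mean ± SD of log2 CPM, n = 9) in the injured 48 h flush and 7.74 ± 0.172 (n = 9) in the uninjured flush, with no difference found between them (exact two-sided permutation p = 0.775, Benjamini-Hochberg adjusted p = 0.797). Of the variance in log2 CPM, the first principal component carried 40.54% and the second carried 13.54%. The first component went with total counts too. Uninjured libraries ran from 190.1 at 1755773 counts (E1B) to 4.652 at 5294304 counts (E3A). The latter lay within the injured 3 h range of -18.81 to 55.33. Total counts and genes detected were higher in injured 48 h than in uninjured flushes (exact tests, adjusted p = 0.00225 and 0.0017). Depth and group were not parted on this component.

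Most marker scores of other cells were higher in the injured flush. At 48 h the score of smooth muscle markers was higher than in the uninjured flush by 1.95 log2 units, that of fibroblasts by 2.24, of macrophages by 3.19, of platelets by 1.73 and of neutrophils by 1.67 (exact two-sided permutation tests, Benjamini-Hochberg adjusted p = 0.00074, 0.00227, 0.00074, 0.00074 and 0.000988). Scores of lymphatic endothelial cells (2.78), B cells (2.25) and adipocytes (2.12) were higher as well (adjusted p = 0.00074, 0.000988 and 0.0342, exact tests). So were those of erythroid cells (1.51, adjusted p = 0.00819) and of T and NK cells (1.31, adjusted p = 0.012), neither of which passed as a list with camera. Against all other genes, the same markers did not pass as lists for fibroblasts (7 of 11 higher, 1 lower, camera adjusted p = 0.254), platelets (5 of 11 higher, 2 lower, 0.486), neutrophils (7 of 13 higher, 1 lower, 0.517), lymphatic endothelial cells (0.0862), B cells (0.0675) or adipocytes (0.237). The list of B cells passed with a block for mouse (camera adjusted p = 0.0229) and without batch 1 (0.032), and that of lymphatic endothelial cells without batch 1 (0.0256). In batch 3 alone, the lists of fibroblasts (camera adjusted p = 0.0286), neutrophils (0.0023) and erythroid cells (0.00893) passed. At 3 h the largest differences from the uninjured flush were in neutrophils (3.63), erythroid cells (3.30), platelets (3.21) and B cells (3.16), at adjusted p = 0.00225, 0.0036, 0.00225 and 0.00225 in the same exact tests. The scores of lymphatic endothelial cells (1.98, adjusted p = 0.00225), of adipocytes (3.10, 0.012) and of endothelial cells (0.22, exact p = 0.025, adjusted p = 0.0391) were also higher at 3 h than in the uninjured flush. The mesothelial score was lower at 3 h (-0.67, adjusted p = 0.00225, all 5 libraries below all 9) and did not differ at 48 h (0.57, adjusted p = 0.578). Its injured 48 h mean took in replicate E2A at 6.316, against -0.184 to 2.487 in the others. The Schwann cell score did not differ at 3 h (-0.21, adjusted p = 0.486) and was higher at 48 h (0.77, adjusted p = 0.0161). Its 3 h mean took in replicate C3B at 0.6701, against -1.069 to -0.6336 in the others, and was not tested without it. From 3 h to 48 h the macrophage score increased by 1.97 (adjusted p = 0.0036), while scores of neutrophils, platelets and erythroid cells differed by -1.97, -1.48 and -1.79 (adjusted p = 0.0161, 0.00225 and 0.0198, exact tests). The smallest p these exact tests can give is 4.11e-05 for the 48 h injury comparison and 5e-04 for the other 2. They do not use the pairing by mouse, so the p-values at 48 h against uninjured treat paired flushes as independent.

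**Figure D1:**
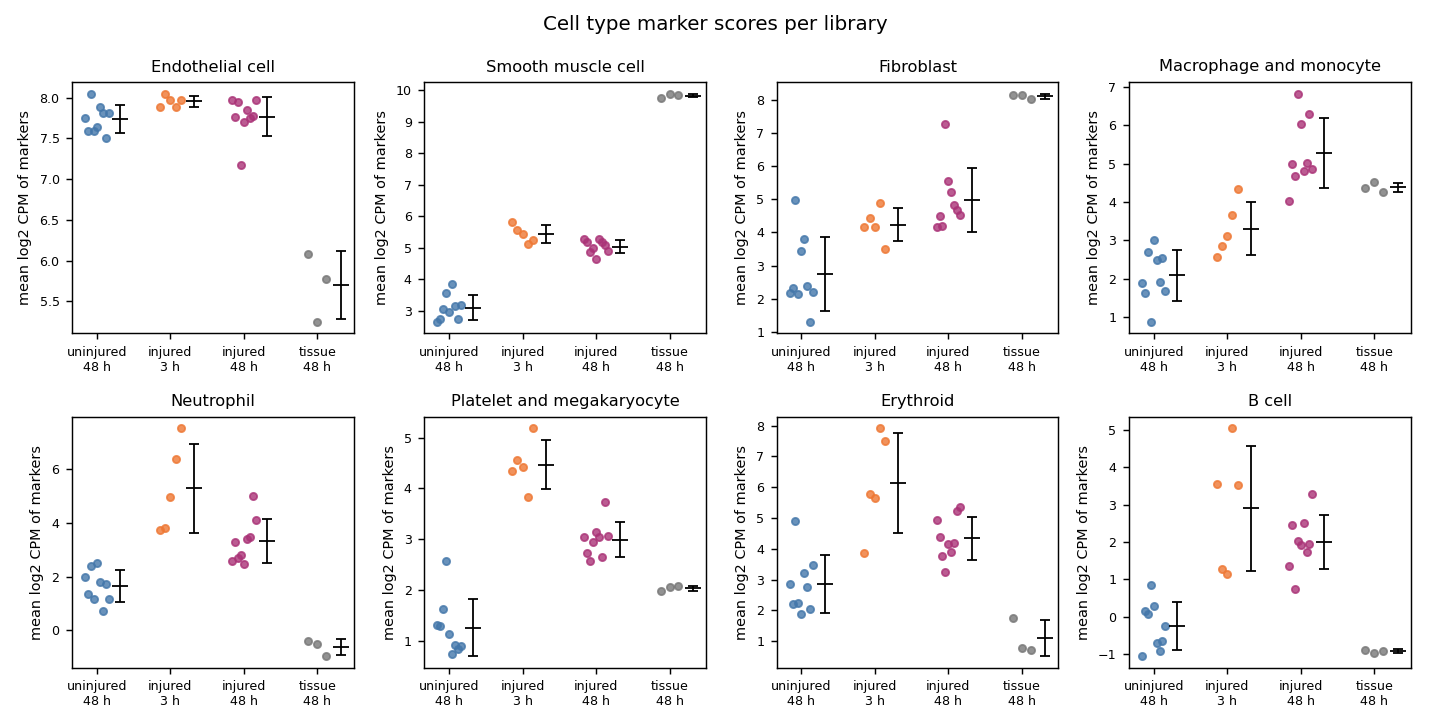
Marker scores of cell types in each library, as mean log2 CPM of the tested markers. Points are libraries, grouped by the 4 sample groups.

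At 48 h after wounding, endothelial cells next to a denuded area are expected to divide and to rebuild the layer. In the flush of the wounded aorta the genes of cell division showed the broadest change. The comparison was made with the uninjured flush of the same mice, which came from the thoracic segment. It found 3421 genes higher and 2501 lower of 13884 tested (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), of which 2150 and 1252 changed at least 2-fold. The authors' deposited table listed 3746 higher and 3052 lower, and 3224 and 2457 genes were on the same side in both.

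All 28 tested genes of mitosis were higher at 48 h (camera adjusted p = 2.72e-19, and adjusted p = 0.106 with an estimated correlation). Mki67 (chromosome 7, 135689784 to 135716361, GRCm38, GENCODE M21) rose from 37.9 ± 18.3 to 457 ± 102 CPM, a log2 fold change of 3.61 ± 0.28 (edgeR adjusted p = 7.17e-10). Aspm (chromosome 1, 139454772 to 139494091) and Cenpf (chromosome 1, 189640606 to 189688086) had no count in the 9 uninjured libraries and were at least 664-fold and at least 948-fold higher (edgeR adjusted p = 3.38e-10 and 3.91e-08). Cdk1 was at least 281.7-fold higher (edgeR adjusted p = 1.27e-08), and Anln, Ccna2 and Tpx2 rose by log2 fold changes of 5.64 ± 0.39, 4.99 ± 0.41 and 6.85 ± 0.59 (edgeR adjusted p = 1.16e-10, 1.98e-09 and 3.88e-09). Genes of DNA replication followed, with 24 of 26 higher, 0 lower and 2 not past the threshold (camera adjusted p = 2.88e-09, and adjusted p = 0.221 with an estimated correlation). Among them were Pcna (log2 fold change 1.77 ± 0.18, edgeR adjusted p = 4.14e-08), Mcm4 (1.66 ± 0.17, adjusted p = 4.47e-08), Rrm1 (1.07 ± 0.12, adjusted p = 3.26e-07) and Uhrf1 (at least 273-fold, adjusted p = 1.17e-06).

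Some genes of biosynthesis, stress and sprouting rose as well. Ribosome biogenesis had 23 of 27 genes higher, 1 lower and 3 not past the threshold (camera adjusted p = 1.67e-05, and adjusted p = 0.31 with an estimated correlation). Npm1 was at a log2 fold change of 1.25 ± 0.12, Ncl at 0.75 ± 0.09 and Ddx21 at 0.98 ± 0.14 (edgeR adjusted p = 1.86e-08, 1.09e-06 and 7.69e-06). The integrated stress response and unfolded protein response had 12 of 23 genes higher, 1 lower and 10 not past the threshold (camera adjusted p = 0.0271, and adjusted p = 0.438 with an estimated correlation). Psat1 (chromosome 19, 15904678 to 15947337), which makes serine, rose by a log2 fold change of 7.63 ± 0.73 (edgeR adjusted p = 1.86e-08), and Hspa5 by 0.65 ± 0.10 (adjusted p = 1.48e-05). Cholesterol synthesis had 8 of 15 genes higher, 0 lower and 7 not past the threshold (camera adjusted p = 0.00414, and adjusted p = 0.296 with an estimated correlation). Hmgcs1 (1.31 ± 0.18) and Insig1 (0.89 ± 0.19) rose at edgeR adjusted p = 3.22e-06 and 0.000713. Genes of angiogenic sprouting had 15 of 21 higher, 2 lower and 4 not past the threshold. The list had 16 higher when adjusted over the list alone (camera adjusted p = 0.00414, and adjusted p = 0.253 with an estimated correlation). Apln was at least 197.8-fold higher and Plaur rose by 3.37 ± 0.50 (edgeR adjusted p = 7.28e-06 and 1.04e-05), while Nrp1 (chromosome 8, 128358604 to 128503363) fell by a log2 fold change of 1.35 ± 0.14 (adjusted p = 5.6e-08).

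Genes of endothelial identity moved both ways and, against all other genes, went lower as a list, although their mean level did not differ between the groups. The list had 4 of 26 higher, 12 lower and 10 not past the threshold (camera adjusted p = 0.0209, and adjusted p = 0.632 with an estimated correlation). Eng fell by a log2 fold change of 1.03 ± 0.12, Emcn by 1.39 ± 0.23 and Tek by 0.58 ± 0.11 (edgeR adjusted p = 2.75e-07, 2.98e-05 and 0.000169), and Flt1 rose by 1.90 ± 0.35 (adjusted p = 0.000152). Vwf fell by 0.51 ± 0.11 and Vcam1 by 0.54 ± 0.16 (edgeR adjusted p = 0.000653 and 0.00899), Klf4 fell by 0.72 ± 0.27 (adjusted p = 0.0344), and Pecam1 fell from 5919 to 4229 CPM (adjusted p = 0.00073). Nos3 (-0.45 ± 0.23, edgeR adjusted p = 0.112), Klf2 (-0.66 ± 0.31, adjusted p = 0.0812), Sele (0.64 ± 0.38, adjusted p = 0.17) and Fos (0.19 ± 0.34, adjusted p = 0.661) did not pass the threshold. With the mouse as a block, Nos3 (-0.38, edgeR adjusted p = 0.0236) and Klf2 (-0.69, adjusted p = 0.000114) passed, and Cdh5, higher by 0.26 ± 0.10 without it (adjusted p = 0.0382), did not (0.24, adjusted p = 0.0795). Atf3 rose by 1.36 ± 0.30 (edgeR adjusted p = 0.000817) and Myc 4.45-fold (adjusted p = 0.00104).

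Macrophage genes had 16 of 17 higher, 0 lower and 1 not past the threshold (camera adjusted p = 0.000955, and adjusted p = 0.488 with an estimated correlation). Lyz2 rose by a log2 fold change of 4.12 ± 0.44, Csf1r by 4.73 ± 0.67, Cd68 by 3.66 ± 0.38 and F13a1 by 3.90 ± 0.54 (edgeR adjusted p = 8.19e-08, 4.78e-06, 5.16e-08 and 3.95e-06), and the leukocyte gene Ptprc rose from 90.4 to 198 CPM (adjusted p = 0.00532). Smooth muscle genes had 11 of 16 higher, 0 lower and 5 not past the threshold (camera adjusted p = 0.000429, and adjusted p = 0.176 with an estimated correlation). Tpm2 rose by 4.12 ± 0.42, Myh11 (chromosome 16, 14194535 to 14291372) by 2.57 ± 0.29, Mylk by 1.36 ± 0.17 and Acta2 by 1.26 ± 0.37 (edgeR adjusted p = 4.09e-08, 1.99e-07, 1.04e-06 and 0.00804), and Cnn1 was at least 48.2-fold higher (adjusted p = 2.35e-07). A larger share of wall or blood cells in the flush and a change inside endothelial cells were not parted for these transcripts.

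The largest rises by the fixed rule also took in Ptafr, Maf, Rassf4 and Col6a2, each without a count in the uninjured libraries and at least 360.5-fold, 333-fold, 373.6-fold and 232.7-fold higher (edgeR adjusted p = 3.17e-07, 2.69e-05, 1.37e-05 and 0.000378). The largest falls were in Adgrv1 (chromosome 13, 81095068 to 81633154), which had no count in the injured libraries and was at least 304-fold lower, and in Ahsg (-5.35 ± 0.66), Pax9 (-4.98 ± 0.70, chromosome 12, 56691767 to 56712822), Slc26a4 (-4.28 ± 0.80) and Olfr493 (-4.28 ± 0.96), at edgeR adjusted p = 1e-04, 8.29e-07, 1.02e-05, 0.000235 and 0.00114. Olfr493 belongs to the receptor genes looked at below as possible background of the uninjured libraries. Whether such background carried the other falls was not tested. Posterior Hox genes 6 to 11 had 4 of 11 higher, 0 lower and 7 not past the threshold. The list had 7 higher when adjusted over the list alone (camera adjusted p = 0.0387, and adjusted p = 0.476 with an estimated correlation). Hoxd8 rose by 1.20 ± 0.19, Hoxd9 by 3.03 ± 0.82 and Hoxa11 at least 33.7-fold (edgeR adjusted p = 2.11e-05, 0.0046 and 0.000446). Hox genes mark position along the body, and the injured and uninjured flushes came from different segments. The 3 h flush differs from the uninjured one in segment too, and there the same list had 1 of 11 higher, 0 lower and 10 not past the threshold (camera adjusted p = 0.608). Segment and injury were not parted by these comparisons.

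**Figure D2:**
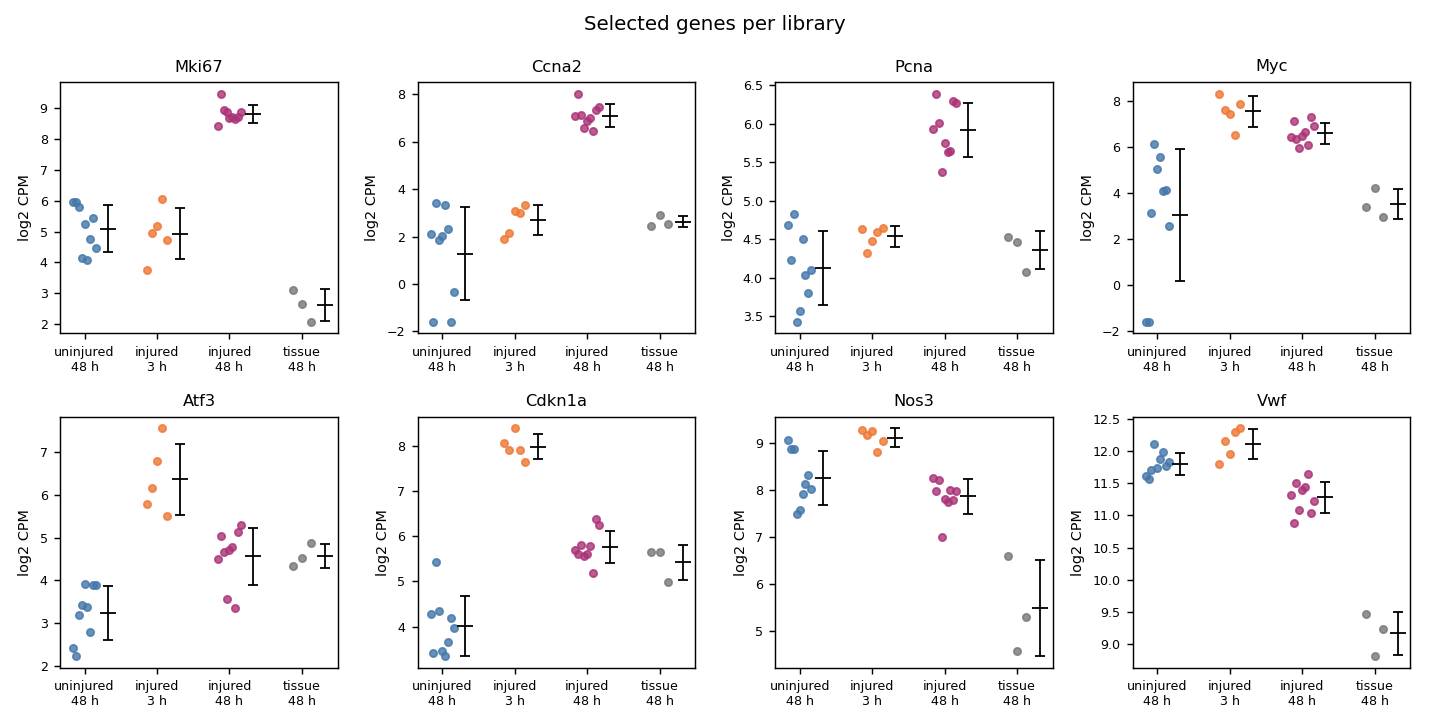
Expression of 8 genes in each library as log2 CPM, with the mean and SD of each group.

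At 3 h after wounding, genes of inflammation and of early stress were among those that rose. The 3 h flushes were compared with the uninjured 48 h flushes of other mice, so segment, mouse and time after wounding all differ between the groups. The libraries held no uninjured flush at 3 h. There were 2230 genes higher and 1535 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), with 1253 and 825 of them at least 2-fold. The authors' deposited table listed 2267 and 2279, with 2049 and 1479 on the same side in both.

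Inflammatory signalling by NF-kB had 16 of 20 genes higher, 0 lower and 4 not past the threshold (camera adjusted p = 1.89e-08). Socs3 rose by a log2 fold change of 6.22 ± 0.58, Ptgs2 (chromosome 1, 150100031 to 150108227) by 4.54 ± 0.51, Tnfaip3 by 1.86 ± 0.25 and Birc3 by 1.49 ± 0.14 (edgeR adjusted p = 1.37e-08, 2.61e-07, 3.08e-06 and 1.35e-08). The p53 list had 7 of 16 genes higher, 1 lower and 8 not past the threshold. The list had 8 higher when adjusted over the list alone (camera adjusted p = 0.00239). Cdkn1a (chromosome 17, 29090976 to 29100727) rose from 17.6 ± 10.3 to 256 ± 49.4 CPM (log2 fold change 3.85 ± 0.26, edgeR adjusted p = 8.48e-11), Mdm2 rose by 0.61 ± 0.09 and Pmaip1 at least 68.2-fold, and Plk2 fell by 2.50 ± 0.30 (adjusted p = 1.17e-05, 3.08e-06 and 8.04e-07). Immediate early genes had 13 of 27 higher, 2 lower and 12 not past the threshold. The list had 14 higher when adjusted over the list alone (camera adjusted p = 0.000232, and adjusted p = 0.326 with an estimated correlation). Fosl2 rose by 2.65 ± 0.20, Fosl1 by 6.27 ± 0.68, Atf3 by 3.25 ± 0.34 and Maff by 2.68 ± 0.34 (edgeR adjusted p = 4.84e-10, 1.55e-07, 8.33e-08 and 1.29e-06), while Fos itself did not pass (0.31 ± 0.40, adjusted p = 0.615).

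Glycolysis and hypoxia genes had 12 of 22 higher, 1 lower and 9 not past the threshold (camera adjusted p = 8.39e-05, and adjusted p = 0.169 with an estimated correlation). Ndrg1 was at 1.25 ± 0.10, Slc2a1 at 1.97 ± 0.37 and Ldha at 0.71 ± 0.13 (edgeR adjusted p = 2.26e-09, 0.000227 and 0.000161). Ribosome biogenesis had 15 of 27 higher, 1 lower and 11 not past the threshold (camera adjusted p = 0.000184, and adjusted p = 0.326 with an estimated correlation). Ddx21 was at 1.08 ± 0.17. The stress response list had 9 of 23 higher, 0 lower and 14 not past the threshold (camera adjusted p = 0.00303, and adjusted p = 0.296 with an estimated correlation). Xbp1 was at 1.10 ± 0.12 and Atf4 at 1.41 ± 0.18 (edgeR adjusted p = 1.91e-07 and 2.3e-06). Genes of flow response and quiescent endothelium (here called flow genes) had 6 of 16 higher, 1 lower and 9 not past the threshold. The list had 7 higher when adjusted over the list alone (camera adjusted p = 0.0152, and adjusted p = 0.476 with an estimated correlation). S1pr1 (chromosome 3, 115710433 to 115715072) rose by 1.82 ± 0.21, Thbd (chromosome 2, 148404466 to 148408188) by 1.06 ± 0.14 and Nos3 (chromosome 5, 24364810 to 24384474) by 0.77 ± 0.26 (edgeR adjusted p = 4.27e-07, 4.16e-06 and 0.0308). Coagulation genes had 9 of 16 higher, 1 lower and 6 not past the threshold. The list had 10 higher when adjusted over the list alone (camera adjusted p = 0.00154, and adjusted p = 0.16 with an estimated correlation), and Tfpi fell by 1.74 ± 0.16 (edgeR adjusted p = 1.58e-08).

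Most tested genes of neutrophils, platelets, erythroid cells and B cells were higher in the 3 h flush. Neutrophil genes had 11 of 13 higher, 0 lower and 2 not past the threshold (camera adjusted p = 3.12e-05, and adjusted p = 0.313 with an estimated correlation). Hdc (chromosome 2, 126593667 to 126619299) was at least 669-fold higher (edgeR adjusted p = 7.63e-07). Platelet genes had 7 of 11 higher, 0 lower and 4 not past the threshold (camera adjusted p = 3.94e-05, and adjusted p = 0.0656 with an estimated correlation). Ppbp was at 6.88 ± 0.57 and Itgb3 at 2.72 ± 0.30 (edgeR adjusted p = 2.15e-09 and 1.82e-07). Erythroid genes had 9 of 10 higher, 0 lower and 1 not past the threshold. The list had 10 higher when adjusted over the list alone (camera adjusted p = 3.94e-05, and adjusted p = 0.31 with an estimated correlation). Hbb-bs was at 3.67 ± 0.58 (edgeR adjusted p = 3.16e-05). B cell genes had 6 of 8 higher, 0 lower and 2 not past the threshold (camera adjusted p = 0.000791, and adjusted p = 0.297 with an estimated correlation). Pax5 was at 5.87 ± 0.81 (edgeR adjusted p = 5.01e-06). Chemokines had 5 of 12 higher, 0 lower and 7 not past the threshold. The list had 9 higher when adjusted over the list alone (camera adjusted p = 0.0212, and adjusted p = 0.221 with an estimated correlation). Ccl2 had 2 counts in the uninjured group and a ratio of 147 (95% counting interval 40.0 to 1222, edgeR adjusted p = 6.72e-06). Smooth muscle genes had 11 of 16 higher, 0 lower and 5 not past the threshold (camera adjusted p = 1.6e-08). Myh11 was at 3.27 ± 0.32 and Mylk at 1.95 ± 0.19 (edgeR adjusted p = 2.59e-08 and 3.46e-08). The camera calls of NF-kB (adjusted p = 0.00952), smooth muscle (0.0374) and p53 (0.0374) held with an estimated correlation, and no other call in this comparison did.

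The largest rises were in Chst3 (chromosome 10, 60181532 to 60219260), Kbtbd11, Col6a3 and Adam8, each at 0 in the uninjured group and at least 436-fold, 336-fold, 674-fold and 514.5-fold higher (edgeR adjusted p = 3.43e-10, 1.46e-08, 2.99e-07 and 2.06e-06). The largest falls were to 0 counts at 3 h, with Pax9 at least 190.1-fold, Ctnna2 at least 170.3-fold and Slc26a4 at least 126-fold lower (edgeR adjusted p = 1.85e-05, 0.00267 and 0.000111). Whether background of the uninjured libraries carried these falls was not tested either. Among genes followed throughout, Cdh5 (chromosome 8, 104101625 to 104144511) rose by 0.74 ± 0.12, Vcam1 by 0.66 ± 0.19 and Myc 8.91-fold (edgeR adjusted p = 3.31e-05, 0.00987 and 8.69e-05). Pecam1 (0.21 ± 0.12), Vwf (0.32 ± 0.13), Klf2 (-0.28 ± 0.37), Klf4 (0.68 ± 0.31), Acta2 (0.31 ± 0.43) and Mki67 (-0.12 ± 0.32) did not pass the threshold (edgeR adjusted p = 0.223, 0.0676, 0.615, 0.105, 0.638 and 0.826), and Cdk1 had 1 count at 3 h. Mitosis genes had 9 of 28 higher, 0 lower and 19 not past the threshold, with a median log2 fold change of 1.04, and did not pass as a list (camera adjusted p = 0.215). Endothelial genes as a list did not pass the threshold (6 of 26 higher, 5 lower, 15 not past the threshold, camera adjusted p = 0.937).

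**Figure D3:**
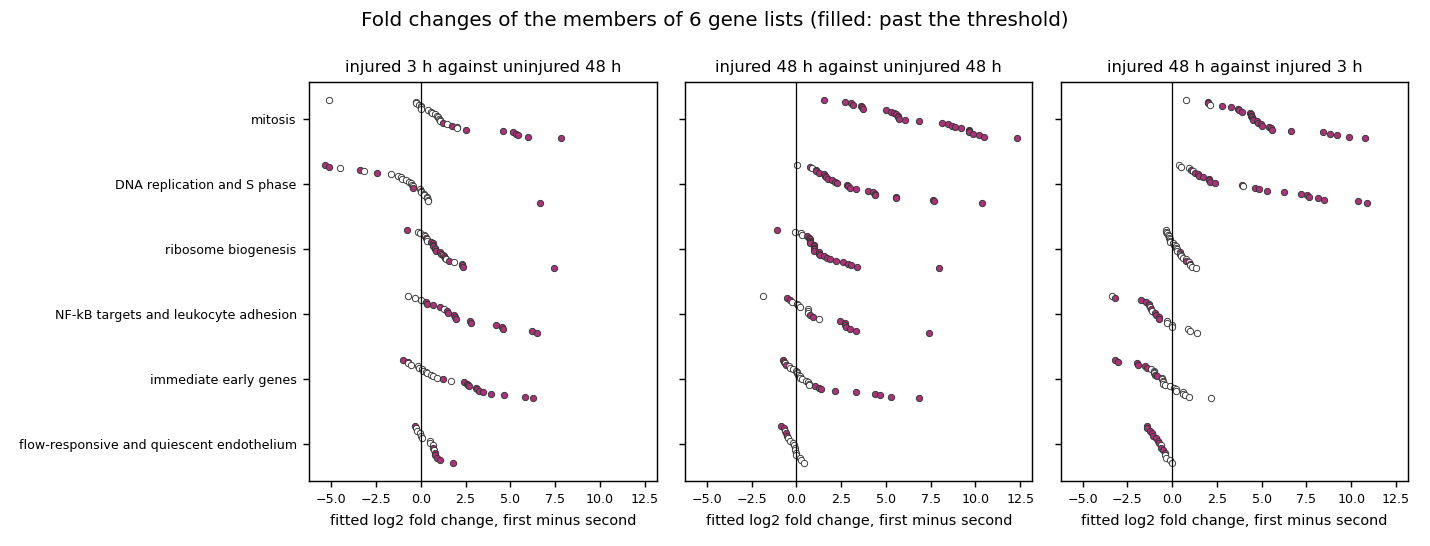
Log2 fold change of the members of 6 gene lists in 3 comparisons. Filled points passed the threshold of 0.05.

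Between 3 h and 48 h, most genes of cell division rose, while parts of the lists of inflammation and flow fell and part of the macrophage list rose. Both groups were abdominal flushes, so segment does not enter this comparison, although the mice differed. It found 1347 genes higher and 1192 lower at 48 h (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 903 and 349 of them at least 2-fold. The authors' deposited table listed 1965 and 1306, with 1294 and 1155 on the same side in both.

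Mitosis genes had 26 of 28 higher, 0 lower and 2 not past the threshold. The list had 27 higher when adjusted over the list alone (camera adjusted p = 6.41e-23, and adjusted p = 0.0656 with an estimated correlation). Mki67 rose by a log2 fold change of 3.74 ± 0.36 from 34.3 ± 19.6 CPM (edgeR adjusted p = 5.43e-08), Anln by 4.42 ± 0.45 and Ccna2 by 4.43 ± 0.51 (adjusted p = 1.19e-07 and 8.35e-07). Foxm1 (chromosome 6, 128362967 to 128376146) and Aspm had no count at 3 h and were at least 382-fold and at least 380.1-fold higher (edgeR adjusted p = 4.96e-10 and 9.64e-09), and Cdk1 went from 1 count to a ratio of 484 (95% counting interval 86.7 to 19100, adjusted p = 1.32e-06). DNA replication genes had 21 of 26 higher, 0 lower and 5 not past the threshold. The list had 23 higher when adjusted over the list alone (camera adjusted p = 2.36e-14, and adjusted p = 0.121 with an estimated correlation). Rrm1 was at 1.48 ± 0.15, Rrm2 at 7.22 ± 1.09 and Mcm5 at least 216.5-fold (edgeR adjusted p = 1.82e-07, 3.66e-05 and 5.9e-06). Cholesterol synthesis had 7 of 15 higher, 0 lower and 8 not past the threshold. The list had 8 higher when adjusted over the list alone (camera adjusted p = 0.000592, and adjusted p = 0.221 with an estimated correlation). Cyp51 was at 1.81 ± 0.36 (edgeR adjusted p = 0.000737). Macrophage genes had 9 of 17 higher, 0 lower and 8 not past the threshold. The list had 12 higher when adjusted over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.648 with an estimated correlation). Mrc1 was at 3.77 ± 0.68 and C1qb at 4.35 ± 0.81 (edgeR adjusted p = 0.000267 and 0.000383), but neither passed with voom (2.63 and 3.16, adjusted p = 0.183 and 0.101).

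Some genes linked to a quiescent endothelium fell in the same interval, although the endothelial score did not differ between the times (exact test, adjusted p = 0.139). Genes of flow response and quiescent endothelium had 0 of 16 higher, 11 lower and 5 not past the threshold (camera adjusted p = 5.15e-07, and adjusted p = 0.211 with an estimated correlation). Thbd was at -1.09 ± 0.14, S1pr1 at -1.42 ± 0.21, Ptgis at -0.90 ± 0.14, Nos3 at -1.22 ± 0.26 and Klf4 at -1.40 ± 0.31 (edgeR adjusted p = 5.43e-06, 2.8e-05, 4.23e-05, 0.00152 and 0.00194). Endothelial genes had 4 of 26 higher, 11 lower and 11 not past the threshold, with 5 higher and 12 lower when adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.596 with an estimated correlation). Vwf was at -0.83 ± 0.13, Pecam1 (chromosome 11, 106654217 to 106750628) at -0.69 ± 0.12 and Cdh5 at -0.47 ± 0.12 (edgeR adjusted p = 4.11e-05, 0.000207 and 0.00552). Junction genes had 0 of 17 higher, 8 lower and 9 not past the threshold. The list had 10 lower when adjusted over the list alone (camera adjusted p = 0.00841, and adjusted p = 0.376 with an estimated correlation). F11r was at -0.50 ± 0.09 (edgeR adjusted p = 0.000237). NF-kB genes had 0 of 20 higher, 9 lower and 11 not past the threshold. The list had 13 lower when adjusted over the list alone (camera adjusted p = 1.89e-06). Socs3 was at -3.20 ± 0.49, Nfkbia at -1.47 ± 0.20 and Vcam1 at -1.20 ± 0.18 (edgeR adjusted p = 4.11e-05, 1.02e-05 and 4.23e-05). Immediate early genes had 0 of 27 higher, 8 lower and 19 not past the threshold (camera adjusted p = 0.00198, and adjusted p = 0.444 with an estimated correlation). Fosl2 was at -1.40 ± 0.20, Atf3 at -1.88 ± 0.32 and Klf6 at -0.96 ± 0.17 (edgeR adjusted p = 1.26e-05, 0.000155 and 0.000299).

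The largest falls were in Mt2 (-5.83 ± 0.44, chromosome 8, 94172664 to 94173568), Fgfr4 (-5.82 ± 1.28) and Sphk1 (chromosome 11, 116530925 to 116536674, 0 counts at 48 h and at least 292-fold lower), at edgeR adjusted p = 9.96e-10, 0.00198 and 0.000736. Platelet genes had 0 of 11 higher, 4 lower and 7 not past the threshold. The list had 8 lower when adjusted over the list alone (camera adjusted p = 2.66e-06). Ppbp was at -2.55 ± 0.46 (edgeR adjusted p = 0.000269). Neutrophil genes had 0 of 13 higher, 9 lower and 4 not past the threshold. The list had 10 lower when adjusted over the list alone (camera adjusted p = 4e-06, and adjusted p = 0.296 with an estimated correlation). Il1r2 was at -3.14 ± 0.44 (edgeR adjusted p = 1.38e-05). Erythroid genes had 0 of 10 higher, 7 lower and 3 not past the threshold. The list had 8 lower when adjusted over the list alone (camera adjusted p = 1.67e-05, and adjusted p = 0.31 with an estimated correlation). Hbb-bs was at -2.63 ± 0.56 (edgeR adjusted p = 0.00153). The falls of S100a9 (-2.40 ± 0.54) and Cxcr2 (-2.73 ± 0.58) rested on replicate C3B, without which they were -1.28 (edgeR adjusted p = 0.0744) and -1.47 (adjusted p = 0.0725). Rnase1 (-5.48 ± 1.26) was -2.52 without replicate C2A (edgeR adjusted p = 0.172). Myc, at 199 CPM and then 99.6 CPM, Myh11 (-0.69 ± 0.30), Acta2 (0.95 ± 0.44) and Sele (0.98 ± 0.47) did not pass the threshold (edgeR adjusted p = 0.19, 0.116, 0.141 and 0.148). With voom Myc (-0.90), Myh11 (-0.81) and Acta2 (0.93) did (adjusted p = 0.00282, 0.00334 and 0.0274), as did Myc (-1.02) and Acta2 (0.92) in fits of these 2 groups alone (edgeR adjusted p = 0.00674 and 0.00449). Smooth muscle genes had 0 of 16 higher, 2 lower and 14 not past the threshold (camera adjusted p = 0.0146, and adjusted p = 0.313 with an estimated correlation), and their score differed by -0.40 (exact test, adjusted p = 0.0161). Ptprc (-0.14 ± 0.36), Klf2 (-0.38 ± 0.36) and Fos (-0.12 ± 0.40) did not pass either. Posterior Hox genes 6 to 11 had 1 of 11 higher, 0 lower and 10 not past the threshold within this segment (camera adjusted p = 0.0467, and adjusted p = 0.489 with an estimated correlation). Hoxd8 was at 0.83 ± 0.23 (edgeR adjusted p = 0.0108), and at 0.65 after thinning to equal depth (adjusted p = 0.195). Hoxa11 did not pass (2.88 ± 1.27, edgeR adjusted p = 0.127), but did with voom (3.72, adjusted p = 4.06e-05). With an estimated correlation the calls of NF-kB (camera adjusted p = 0.0374) and platelets (0.0177) held.

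The flush was compared with the vessel wall that remained, to see which genes belong to the luminal layer. Both came from the injured abdominal aorta at 48 h, with 9 flush and 3 tissue libraries. The wall had higher scores of smooth muscle and fibroblasts, and the flush of endothelium and several blood cells. Olfactory and vomeronasal receptor genes, looked at below as possible background, held 863 CPM of the raw total in the flush and 48.5 in tissue. Whether such background carried genes called higher in the flush was not tested. There were 3050 genes higher in the flush and 1880 lower (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), 2226 and 1121 of them at least 2-fold, against 3019 and 2148 in the authors' deposited table, with 2756 and 1676 on the same side in both.

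Smooth muscle genes had 0 of 16 higher, 15 lower and 1 not past the threshold (camera adjusted p = 2.97e-18). Myh11 fell from 9006 ± 819 CPM in tissue to 171 ± 66.4 in the flush (log2 fold change -5.72 ± 0.35, edgeR adjusted p = 1.06e-12). Itga8 (chromosome 2, 12106632 to 12301922) was at -7.07 ± 0.42, Cnn1 at -6.82 ± 0.29, Synpo2 at -4.18 ± 0.22, Mylk at -3.86 ± 0.21, Acta2 at -3.81 ± 0.46 and Cald1 at -2.88 ± 0.12 (adjusted p = 7.6e-13, 1.97e-12, 8.7e-14, 1.41e-13, 3.29e-07 and 2.19e-15). Fibroblast genes had 0 of 11 higher, 10 lower and 1 not past the threshold (camera adjusted p = 3.6e-08, and adjusted p = 0.121 with an estimated correlation). Dpt was at -3.63 ± 0.78 and Pi16 at -2.26 ± 0.34 (edgeR adjusted p = 0.000603 and 8.25e-06). TGF-beta genes had 2 of 18 higher, 8 lower and 8 not past the threshold. The list had 10 lower when adjusted over the list alone (camera adjusted p = 0.000105). Zeb1 was at -1.25 ± 0.07 and Tgfbr1 at -1.64 ± 0.13 (edgeR adjusted p = 5.73e-13 and 2.59e-10). Matrix genes had 4 of 27 higher, 10 lower and 13 not past the threshold (camera adjusted p = 0.00451, and adjusted p = 0.444 with an estimated correlation). Sparc was at -1.03 ± 0.18 (edgeR adjusted p = 5.22e-05). The largest falls were in Fibin, Speg and Jph2, without a count in the flush and at least 2782-fold, 2472-fold and 2282-fold lower (edgeR adjusted p = 1.23e-05, 2.12e-05 and 2.91e-05).

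Endothelial genes had 25 of 26 higher in the flush, 0 lower and 1 not past the threshold. The list had 26 higher when adjusted over the list alone (camera adjusted p = 4.06e-14, and adjusted p = 0.106 with an estimated correlation). Ecscr rose by a log2 fold change of 2.91 ± 0.17, Egfl7 by 2.74 ± 0.18, Esam by 2.16 ± 0.16, Vwf by 2.10 ± 0.18 and Pecam1 by 1.85 ± 0.17 (edgeR adjusted p = 1.02e-12, 6.83e-12, 4.72e-11, 6.45e-10 and 2.22e-09). Flow genes had 13 of 16 higher, 1 lower and 2 not past the threshold. The list had 14 higher when adjusted over the list alone (camera adjusted p = 1.37e-05, and adjusted p = 0.264 with an estimated correlation). S1pr1 was at 3.00 ± 0.32, Klf2 at 2.62 ± 0.51 and Nos3 at 2.18 ± 0.37 (edgeR adjusted p = 3.13e-08, 0.000236 and 4.21e-05). Junction genes had 13 of 17 higher, 1 lower and 3 not past the threshold (camera adjusted p = 3.94e-05, and adjusted p = 0.211 with an estimated correlation). F11r was at 2.11 ± 0.12 (edgeR adjusted p = 5.5e-13). Notch genes had 12 of 19 higher, 1 lower and 6 not past the threshold (camera adjusted p = 0.00119, and adjusted p = 0.31 with an estimated correlation). Sox17 was at 2.85 ± 0.22, Gja5 at 2.81 ± 0.24 and Heyl at -5.81 ± 0.54 (edgeR adjusted p = 8.95e-11, 9.29e-10 and 3.34e-09). Klf4 (0.99 ± 0.40) and Atf3 (0.10 ± 0.40) did not pass the threshold (edgeR adjusted p = 0.0553 and 0.888). Klf4 passed with the stricter filter (1.00, edgeR adjusted p = 0.0499), the DESeq2 Wald test (0.91, 0.046), voom (1.29, 0.000468), only these 2 groups (0.93, 0.0422), batch as a covariate (1.11, 0.0187) and without tissue E1A (1.57, 0.0123).

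Many transcripts of cell division and of immune activation were also higher in the flush than in the wall, without showing which cells carried them. Mitosis genes had 26 of 28 higher, 0 lower and 2 not past the threshold. The list had 27 higher when adjusted over the list alone (camera adjusted p = 1.53e-10, and adjusted p = 0.253 with an estimated correlation). Mki67 was at 6.24 ± 0.52 (edgeR adjusted p = 5.77e-10). DNA replication genes had 12 of 26 higher, 0 lower and 14 not past the threshold. The list had 13 higher when adjusted over the list alone (camera adjusted p = 5.43e-06, and adjusted p = 0.328 with an estimated correlation). Rrm1 was at 2.05 ± 0.19 (edgeR adjusted p = 4.89e-09). Antigen presentation had 12 of 15 higher, 0 lower and 3 not past the threshold. The list had 13 higher when adjusted over the list alone (camera adjusted p = 3.45e-05, and adjusted p = 0.221 with an estimated correlation). Psmb8 was at 2.23 ± 0.22 (edgeR adjusted p = 1.27e-08). NF-kB genes had 13 of 20 higher, 0 lower and 7 not past the threshold. The list had 15 higher when adjusted over the list alone (camera adjusted p = 0.000231, and adjusted p = 0.127 with an estimated correlation). Icam1 was at 1.96 ± 0.18, Selp at 2.67 ± 0.32, Vcam1 at 1.91 ± 0.26 and Sele at 3.04 ± 0.65 (edgeR adjusted p = 3.61e-09, 2.1e-07, 1.6e-06 and 0.000556). Interferon genes had 11 of 19 higher, 0 lower and 8 not past the threshold. The list had 12 higher when adjusted over the list alone (camera adjusted p = 0.000232, and adjusted p = 0.264 with an estimated correlation). Parp14 was at 1.41 ± 0.15 (edgeR adjusted p = 6.71e-08). Ptprc rose by 3.75 ± 0.55 and Myc by 3.07 ± 0.78 (edgeR adjusted p = 6.32e-06 and 0.00294). With the mouse as a block, Fos (1.52 ± 0.52, edgeR adjusted p = 0.0234) was 0.85 (adjusted p = 0.088). The smooth muscle (camera adjusted p = 0.00112) and TGF-beta (0.00925) calls held with an estimated correlation.

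No camera call of the 48 h injury comparison held with an estimated correlation, against 3 in the 3 h comparison, 2 between the times and 2 between flush and tissue. With fry, which tests whether the genes of a list move on balance one way, 29, 23, 19 and 28 lists passed in the same order. The injured 3 h flush against tissue gave 3256 genes higher and 2669 lower, and the uninjured flush against tissue gave 3550 and 3408 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05).

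The early and late responses overlapped, but both were measured against the same uninjured libraries, which by itself makes them alike. In all, 1459 genes were higher and 940 lower at both times, where independence would give 549.5 and 276.5. When the uninjured libraries were halved so that each time had its own controls, the median over 10 halvings was 924.5 genes higher at both times (828 to 1045) against 324.4 under independence, and 557 lower (437 to 670) against 150.6. The covariance of the log2 fold changes was 2.572, and 20 simulations with shared controls and no change gave 0.2401 (0.2202 to 0.2736). Covariance grows with the size of the changes. The correlation was 0.5962, against 0.4204 (0.3964 to 0.4511) in the simulations and a median of 0.4794 (0.4139 to 0.5363) with halved controls. The simulations drew each gene on its own, so they hold no background shared by the genes of a library. Segment was shared by both comparisons too, as is any background common to the uninjured libraries, and halving removes neither.

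Olfactory and vomeronasal receptor genes, whose main place of expression is sensory neurons, were looked at as possible background. As CPM of the raw total, they held 3261 in the uninjured flush and 863 in the injured 48 h flush, a difference of -2398 (exact two-sided permutation p = 0.000576, Benjamini-Hochberg adjusted p = 0.0023). The difference between 3 h and uninjured flushes was -2168 (exact p = 0.0165, adjusted p = 0.0283), and between the 2 injured times it was -229 (exact p = 0.414, adjusted p = 0.473). Between injured 48 h flush and tissue (48.5) the difference was 815 (exact p = 0.0364, adjusted p = 0.0535), with all 9 flush libraries above all 3 tissue libraries. Whether these counts are background or transcripts was not settled.

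**Figure D4:**
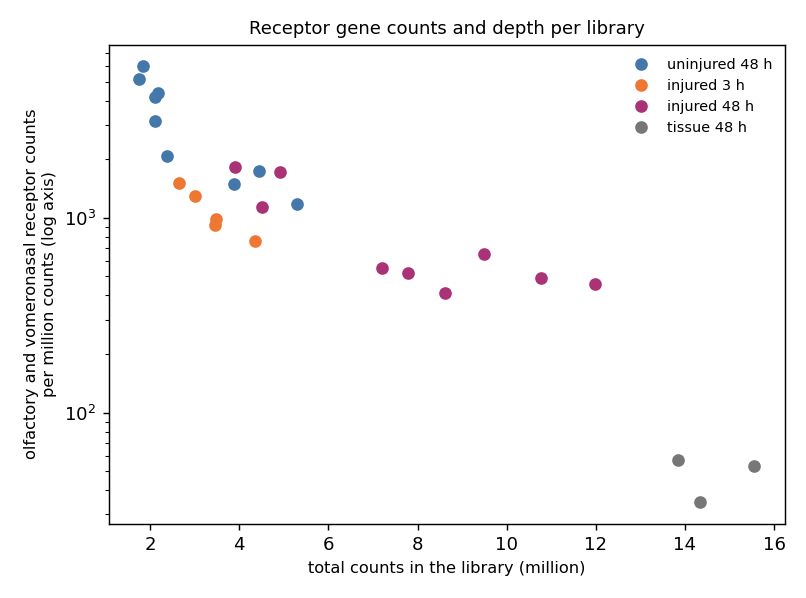
CPM (of the raw total) in olfactory and vomeronasal receptor genes against the total counts of each library. The vertical axis is logarithmic.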

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

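The tests of genomic DNA, of the aortic segment and of macrophages against residual blood were chosen after the results were seen, and the others were written down before. About 1 in 20 groups without any odd library would be marked by the rule used for single libraries, and 60 such tests were made.

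Receptor genes of smell took 3261 CPM of the raw total in the uninjured flush and 863 at 48 h after injury. Genomic DNA stayed open: 23.7% of the 15822 other genes for which an even spread over exons would give at least 20 counts had none in any of the 9 uninjured libraries, which passed the bound of 10% set against it, but so did 30.7% of the 1199 receptor genes themselves, so that bound was wrong for amplified reads. The levels of the 491 tested receptor genes followed the same order in the uninjured and the 3 h flush (Spearman rho = 0.708), in line with a background common to all flush libraries that takes a larger share of some. A response to injury or segment stayed open, since both go with the groups, as would any background that differs between them. Receptor counts did not differ between 48 h and 3 h (exact p = 0.414). Both groups were injured abdominal flushes, so that test cannot decide it. In all, 255 of the 491 receptor genes were called lower at 48 h and 0 higher, and genes of this kind made up 10.2% of the 2501 lower genes.

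Mitosis genes were higher at 48 h than in the uninjured flush. Aortic segment alone does not account for it, because 26 of 28 were also higher at 48 h than at 3 h within the abdominal aorta. A difference in total counts alone does not either, because 28 of 28 passed after every library was thinned to 1755773 counts. Thinning does not make the amount of RNA behind each library equal, and the part of that amount was not tested. Whether macrophages carried the signal could not be told, since mitosis and macrophage scores over the 9 injured 48 h libraries had a Pearson r of -0.284 (exact permutation p = 0.459, Benjamini-Hochberg adjusted p = 0.459, 2 relations), or -0.0541 without replicates E2A and E3B. Bulk RNA cannot show which cells divided.

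Macrophage markers were higher at 48 h than at 3 h, and neutrophil markers were lower. A larger amount of residual blood alone does not account for the macrophages, because the erythroid score moved the other way, by -1.79. That score follows red cells only. The macrophage list also holds monocyte genes, so more monocytes in the blood itself were not excluded. For neutrophils residual blood stayed open. Their score and the erythroid score were both lower at 48 h than at 3 h (-1.97 and -1.79). The 2 scores had a Pearson r of 0.629 over the 9 injured 48 h libraries (exact permutation p = 0.0677, adjusted p = 0.135), and -0.0437 without replicates E3C and E3B. Each batch had 3 of these libraries, too few to test the relation within it. The relation was not tested over the 3 h libraries, where the neutrophil score was higher.

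Each count of called genes was compared with counts from regrouped libraries, and in every case only 1 grouping, the real one, gave as many. Between injured and uninjured 48 h flush the real grouping gave 5922 genes, and 1082 was the highest of the others among 30 groupings, the real one included, of the 256 that part the mice equally. A further 30 groupings of another kind reached 1416. The 3 h injury comparison gave 3765 against 1728 at most in 60 of 2002 groupings (the real one always included), the comparison of the times 2539 against 128 in 60 of 2002, and 3 h flush against tissue 5925 against 1269 in 56. Injured 48 h flush against tissue gave 4930 against 317, and uninjured flush against tissue 6958 against 3, but with 8 groupings that part the mice equally the share cannot go under 0.05, and 52 others reached 76 and 867. Batches 1, 2 and 3 alone gave 3199, 815 and 1444 against 0 in the other groupings, and 4 groupings each are too few in the same way.

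In replicate E2A of the injured 48 h flush, the 10 most abundant genes held 20.54% of the counts, where the others of its group had 6.85 to 9.77%. Its mitochondrial share was 13.42% (others 2.947 to 4.924%). Gm10800 and Gm10801 held 5.783% of its counts (others 0.6685 to 2.118%). Its endothelial score was 7.179 (others 7.701 to 7.973), its fibroblast score 7.272 (others 4.158 to 5.55) and its mesothelial score 6.316 (others -0.184 to 2.487). Pancreas genes held 1011 CPM of the raw total in replicate C2A of the 3 h flush (others 4.141 to 25.37). The platelet score was 2.56 in uninjured E2A (others 0.7448 to 1.617) and 3.726 in injured 48 h E3B (others 2.564 to 3.147). Uninjured E1C had an adipocyte score of 4.848 (others -1.59 to -0.5542) and a mesothelial score of 1.436 (others 0.4447 to 0.9108). The Schwann cell score was 0.6701 in 3 h replicate C3B (others -1.069 to -0.6336). The cause of these was not tested.

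Opposite calls at the 2 times were made for 72 genes higher at 3 h and lower at 48 h, such as Ndrg1, Nrip1 and Ski, and for 45 genes the other way, and with a 2-fold limit at both times these were 1 and 26. For 5 of 10913 genes the 48 h injury difference itself differed between batches (edgeR, Benjamini-Hochberg), among them Thbs1 and Glis3 (adjusted p = 0.00668 for each), Serpinb6b (0.0338) and Zbtb46 (0.0363), and these were named after the values were seen.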

How the results depend on the processing

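The alternatives listed with the methods were fixed at the start. Thinning to equal depth, the limit on shallow uninjured libraries, leaving out replicate E2A and the limit of 20 CPM were added after seeing the data. A count of genes is printed here where it moved by more than 1.5-fold.

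With voom and quality weights, 2366 genes were higher and 2221 lower at 48 h than at 3 h, 4631 and 3871 differed between injured 48 h flush and tissue, 4347 were lower in 3 h flush than in tissue and 5833 in uninjured flush. Fits of only 2 groups gave 2238 higher at 48 h against uninjured, 1297 higher at 3 h and 2961 lower in injured 48 h flush than in tissue. At 48 h against uninjured, Klf4 was lost with voom (-0.42, adjusted p = 0.151) and with no filter (-0.67, 0.054), Cdh5 with DESeq2 size factors (0.22, 0.0726), 2 groups (0.22, 0.102) and thinning (0.24, 0.105), while Klf2 passed with the Wald test (-0.72, 0.0404) and Nos3 with batch as a covariate (-0.38, 0.0466). At 3 h, Klf4 (0.79, 0.0402) and Vwf (0.29, 0.0484) passed with voom, and Nos3 was lost with size factors (0.70, 0.0528).

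Batch 1 alone gave 1812 genes higher and 1387 lower at 48 h against uninjured, batch 2 alone 521 and 294, batch 3 alone 920 and 524, and 1303 were lower without batch 1. The YAP and TEAD list did not pass in all batches together (camera adjusted p = 0.636). It passed in the same direction in batch 1 alone (adjusted p = 0.018) and in the other direction in batch 2 alone (adjusted p = 0.0367). Of the lists called at 48 h, posterior Hox lost its call without batch 1 (0.0864), without batch 2 (0.0716), in batch 2 alone (0.181) and in batch 3 alone (0.246). Endothelial genes lost it without batch 2 (0.0717), the stress response without batch 1 (0.0502) and in batch 2 alone (0.169), and sprouting (0.537) and smooth muscle (0.0517) in batch 2 alone. Fewer mice leave less power, and the cause of the spread between batches was not tested.

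With the mouse as a replicate block, the paired fit gave 3562 genes higher and 2265 lower at 48 h against uninjured, and 13 lists passed where 10 had, adding B cell (camera adjusted p = 0.0229), chemokine (0.0361) and flow genes (0.0197). Hoxc10 was lost (5.75, edgeR adjusted p = 0.0958). Against tissue, the block also took the calls of Dkc1 (0.54, adjusted p = 0.196), Il7r (3.25, 0.0785) and Nop56 (0.85, 0.109). Apart from these and from the calls of Cdh5, Klf2, Nos3 and Fos given above, it changed no other printed call among those it was run for, which were genes taken by the naming rule in these 2 comparisons and the lists at 48 h against uninjured. The lists of flush against tissue were not run with it.

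Thinned to equal depth, 861 genes were higher and 777 lower at 48 h than at 3 h, so depth limits how many genes pass. With only the 3 deepest uninjured libraries (at least 3878345 counts, 6 left out), 1616 were higher and 774 lower at 48 h against uninjured, and 1420 were higher at 3 h. In that setting Pecam1 (-0.46, edgeR adjusted p = 0.0513), Vcam1 (-0.31, 0.409), Klf4 (-0.77, 0.173), Hoxd9 (1.85, 0.19), Insig1 (0.61, 0.0708) and Cdh5 (0.19, 0.482) lost their calls at 48 h, as did Ldha (0.51, 0.0504) and Nos3 (0.75, 0.125) at 3 h. That setting also has fewer mice, and whether depth or number lost these calls was not tested. Among genes of at least 20 CPM, 1949 were higher at 48 h against uninjured, 731 were higher at 48 h than at 3 h, and 1798 were higher in injured 48 h flush than in tissue. The same limit left 1994 higher and 1724 lower in 3 h flush, and 2010 and 2132 in uninjured flush.

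With an estimated correlation, 0, 3, 2 and 2 lists passed in the 4 main comparisons, where 10, 17, 15 and 18 had, and fry passed 29 in the 48 h injury comparison and 28 between flush and tissue. With a 2-fold limit, 859 genes were higher and 388 lower at both times.

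Leaving out 1 replicate of the 3 h group gave 1790 to 2099 genes higher and 1028 to 1358 lower than uninjured. Hoxc10 changed sign with voom (-0.82), and Ciita, carried by 3 h replicate C2C, ran from 0 without it to 6.98 without C3B. Nos3 lost its 3 h call without any 1 of C1A, C1B, C2A or C3B (0.73 to 0.80, edgeR adjusted p = 0.0507 to 0.0666), and Vcam1 without C1A (0.52, 0.0549). Without injured 48 h replicate E2A, Klf4 lost its call against uninjured (-0.67, 0.0553), Sele gained one (0.80, 0.0395) and Hoxc10 was lost (3.48, 0.0938). Col6a2 and Maf, which have no uninjured count, kept their calls, and Slc26a4 kept its call at -4.97. Against 3 h, Myh11 (-0.83, 0.0462) passed without it, as did Sele (adjusted p = 0.0363). Without C3B, Adam8 was still higher at 3 h, against uninjured libraries without a count. Rrm2 had all 5 of its 3 h counts in C2C, and without tissue E1A, Klf2 was 3.48 and Nos3 2.94. Fos in flush against tissue was lost without any 1 tissue replicate (1.28 to 1.67) and with 2 groups (1.46, 0.0563). Vwf passed at 3 h without C1A (0.39, 0.0366). Of the named genes called, 55 of 63, 65 of 80, 52 of 65 and 77 of 86 kept their call in the settings run for them in the 4 main comparisons. Batches alone or left out were not run for named genes.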

Other observations

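More genes of the circadian clock were lower than higher at 48 h after injury, in groups that differ in segment too. Of 16 tested, 4 were higher and 8 lower at 48 h than in the uninjured flush, with 4 not past the threshold, at a median log2 fold change of -0.65. The list did not pass with camera (adjusted p = 0.0907, and adjusted p = 0.495 with an estimated correlation), but passed toward lower with fry (adjusted p = 0.016). With camera it also passed without batch 1 (adjusted p = 0.0194), in batch 2 alone (0.00426) and in batch 3 alone (0.00436), and not in the other batch settings or with the mouse as a block. Nr1d2 fell by a log2 fold change of 0.96 ± 0.12, Per2 by 1.05 ± 0.17 and Tef by 1.04 ± 0.17 (edgeR adjusted p = 1.02e-06, 2.2e-05 and 3.25e-05), while Nfil3 rose by 4.05 ± 0.70 (adjusted p = 6.39e-05). These 4 members had the smallest p of the list, and the other settings were not run for them as named genes. At 3 h, 4 were higher and 5 lower than in the uninjured flush (camera adjusted p = 0.629). The hour at which each mouse was killed is not given in the sources used here, although both 48 h flushes came from the same animals, so time of day cannot differ between them by more than the order of collection.

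Mitosis genes were higher at 48 h than at 3 h within 1 segment (26 of 28), which could reflect entry of cells into the cycle between these times. Counting labelled nuclei among endothelial and macrophage cells would part the cells that divide, because the correlation with the macrophage score (-0.284) left this open. A control flush of unwounded abdominal aorta would part injury from segment.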
